A study of Mus musculus with 5 samples.

How the data were processed

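RNA from mouse cells was hybridised to 5 single-colour (Cy3) 60-mer expression arrays of the same Agilent design, 1 array per sample. Per the file headers, the design is annotated on the mouse genome build mm9. The authors scanned the arrays and extracted the spots with Agilent Feature Extraction 10.7.1.1, and the deposited array files give the processed signal of each spot as an intensity, background-subtracted and detrended within the array but not scaled between arrays. The deposited value table holds log2 values with 1 value per probe. Its 5 columns shared 1 distribution (median 5.64 in each) and correlated at 0.995 to 0.999 with log2 of each array's own processed signal, so it was read as quantile normalised; the step itself is not described in the labels.

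Each array held 62976 spots, of which 59305 were not controls. The share of those spots that Feature Extraction marked well above background was 57.6% on the MEF array, 49.1% on ciNPC p5, 48.0% on ciNPC p13 replicate 1, 54.1% on ciNPC p13 replicate 2 and 55.2% on NPC. The slope of the spike-in controls was 0.939, 0.939, 0.915, 0.803 and 0.987 in the same order, and the value of ciNPC p13 replicate 2 lay outside the range that the software accepts. The number of arrays limits the precision of every value.

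The values analysed were log2 of the processed intensity minus the 75th percentile of the array, averaged over the spots of a probe after spots marked as non-uniform or population outliers were removed. Probes were named through the accession given in the files where the reference table of mouse genes (assembly GRCm38.p6, used for names only) held it, and otherwise through the symbol in the files. Of 55681 probes, 29676 carried a symbol of the reference table, 26582 of all probes through their accession, and 26005 did not. These probes covered 21983 genes. Each gene was represented by the probe with the highest mean over the 5 arrays, and 16229 genes were kept whose probe was well above background on every array of at least 1 of the 4 groups (MEF, ciNPC p5, ciNPC p13, NPC). Probe coordinates are those of the files on mm9.

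The comparisons, their tests, the gene lists and the rule for naming genes were fixed before the data were examined. ciNPC against MEF and ciNPC against NPC came from 1 fit in limma 3.58.1 (R 4.3.3; lmFit, then eBayes with an intensity trend) with the 3 ciNPC arrays as 1 cell type, which left 2 residual degrees of freedom. ciNPC p13 against p5 came from a fit with 4 groups and 1 residual degree of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 2-fold, and "higher" or "lower" as a count refers to genes that passed. The lone MEF and NPC arrays were assumed to vary like the ciNPC arrays. The labels do not say whether the p13 arrays came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. NPC against MEF, with 1 array each, was described without a test, by the genes at least 4-fold apart after values under the lowest well-above-background signal of their array were raised to it (the floor). Where the dimmer cell type was under background, a fold is given as a lower bound against that floor. List medians use the measured values of all members tested, dim ones included, and are given at the floor as well where that moved them most.

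The position of a ciNPC array between MEF (0) and NPC (1) was the median over genes of its floored log2 distance from MEF divided by that of NPC, for genes at least 4-fold apart in these cell types. Pearson's r was computed over the genes tested for the 10 pairs of arrays; genes are not independent replicates. The 26 gene lists were neural progenitor, fibroblast, neuron, astrocyte, oligodendrocyte, pluripotency, hypoxia response, TGF-beta response, Wnt response, Notch response, cell cycle, cell-cycle inhibitor, epithelial, neural crest, macrophage, endothelial, muscle, Hox, forebrain, midbrain and hindbrain, sex-linked, imprinted, interferon, cholesterol synthesis, immediate-early and housekeeping genes; some genes stand in more than 1 list. The median of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. These lists drew genes singly, so the percentile does not measure the spread between arrays.

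Genes were named by rule. For ciNPC against MEF or NPC these were the 10 highest and 10 lowest past the threshold, well above background in the brighter cell type and at least 2-fold apart the same way on each of the 3 ciNPC arrays. The rule took the 5 highest and 5 lowest for p13 against p5, for NPC against MEF and for genes past the threshold the same way against both. It also took up to 5 genes per class whose position was under 0.25 on all 3 ciNPC arrays. Up to 4 members per list and comparison, and Sox2, Pax6, Nes, Olig2, Fabp7, Col1a1, Thy1, Twist2, Pou5f1 and Nanog, were named as well. Predicted and clone names were left out. Of 264 genes named this way, 50 had more than 1 probe above background, and only Kdr had probes at least 2-fold apart in opposite directions against MEF.

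The tests were checked on simulated data: 10 simulations per comparison with 16229 genes and 50 changed genes per size. Changes of 2 and 4 log2 units were recovered at 72.6% and 81.4% for ciNPC against MEF, 72.4% and 80.8% for ciNPC against NPC, and 76.8% and 85.2% for p13 against p5, with a mean of 7.4, 9.1 and 21 false calls. Changes of 1 log2 unit were recovered at 29%, 32.2% and 34%. Alternatives tried were quantile normalisation, normexp background correction (offset 50) with quantile normalisation, the authors' value table, no filter on dim probes, only genes above background on all 5 arrays, the mean of all probes of a gene, a floor, no intensity trend, a fit with 4 groups, leaving out each ciNPC array, a size rule for p13 against p5, a 2-fold size for NPC against MEF, Spearman's rho, and, added after the data were seen, a percentile over detected probes and all names on the array. Summaries and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The 26005 probes outside the reference table were left out of the comparisons.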

Results

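Gene expression was measured in 5 mouse samples. 1 array held mouse embryonic fibroblasts (MEF), 1 held neural progenitor cells taken from brain (NPC, the control), and 3 held chemically induced neural progenitor cells (ciNPC), cells converted from fibroblasts with small molecules under low oxygen. Of the ciNPC arrays, 1 was from passage 5 (p5) and 2 were from passage 13 (p13). The MEF and NPC arrays shared slide 1 and scan 1, and all 3 ciNPC arrays shared slide 2 and scan 2. For any single gene, a difference of ciNPC from MEF or NPC and a difference between slides cannot be told apart. A slide effect alone would move ciNPC the same way against MEF and NPC. Of 4967 genes that passed against MEF, 4077 (82.1%) lay within 2-fold of NPC. These values argue against slide as the only cause of most differences from MEF, but not of those from NPC. A gene just past 2-fold from MEF may lie just within 2-fold of NPC, so a part for slide is not excluded. NPC against MEF and p13 against p5 each lay within 1 slide.

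NPC and MEF mark the ends between which ciNPC were placed. The oligodendrocyte lineage factor Olig1 was at least 1850-fold higher in NPC than in MEF and Bex2 at least 2140-fold, and the progenitor factor Sox3 was at least 1070-fold higher. The proteoglycan gene Bcan was higher by 10.14 log2 units and the non-coding RNA Pantr1 by 10.21. In the other direction, the log2 difference of NPC from MEF was -13.30 for the collagen gene Col1a2 and -12.91 for smooth muscle actin Acta2. Itga11 was at least 5420-fold, Col1a1 at least 5030-fold and Cnn1 at least 4360-fold lower in NPC. In all, 2937 genes were at least 4-fold apart, 1300 higher and 1637 lower in NPC. Between the p13 arrays 46 genes were that far apart. No test was run for this pair, with 1 array each.

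ciNPC against MEF asks how far the cells had left the fibroblast state. Olig1 was at least 1250-fold higher in ciNPC (adjusted p 4.73e-07, 3 ciNPC arrays against 1), Bex2 at least 1660-fold (9.79e-07) and Sox3 at least 757-fold (1.17e-06). The stem cell factor Sox2, probed on chromosome 3 at 34550773 to 34550832 (mm9), rose at least 78.7-fold (2.02e-06), and Olig2 at least 217-fold (9.79e-07). The fatty acid binding protein gene Fabp7 rose by 9.69 log2 units (SE 0.16, adjusted p 5.34e-07), Bcan by 9.72 (SE 0.14) and the intermediate filament gene Nes by 2.11 (SE 0.12). The eye and forebrain factor Pax6 rose at least 6.63-fold (adjusted p 0.000207). Prkcb, Prr18, Igsf21, Amph and Pantr1 completed the 10 highest genes.

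The lowest genes against MEF included Gzme, at least 62.7-fold lower (adjusted p 0.001), and Ndufa4l2, at least 57.5-fold lower (0.000603). Fam20a, Itga11 and Runx1 differed by -5.99 (SE 0.26), -5.97 (SE 0.26) and -5.78 (SE 0.25), and Apol8, Agbl3, Fcgrt, Soat2 and Meox1 were also among the 10 lowest. The surface marker Thy1 differed by -3.60 (SE 0.17, adjusted p 2.46e-05) and Col1a1, probed on chromosome 11 at 94813115 to 94813174, by -2.19 (SE 0.16). The mesenchymal factor Twist2 differed by -0.84 (SE 0.22), under the 2-fold limit. Of 16229 genes tested, 4967 passed against MEF, 2484 higher and 2483 lower.

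Marker lists gave the same contrast by cell type. Neural progenitor genes had a median log2 difference from MEF of 3.65, or 3.16 with dim genes at the floor, with 33 of 40 members higher and 1, Gli3, lower (2 without either p13 array). The forebrain median was 2.78, or 1.23 at the floor, with 8 of 15 higher and 2 lower (5 lower without p13 replicate 2). Lhx6 was 1 of those 2, at -2.12, but the mean of its probes gave 0.16. Astrocyte genes had a median of 1.26 (8 higher, 1 lower of 16, and 0 lower without p13 replicate 2), led by Sparcl1 at 5.75. Neuron genes had 0.55 (7 higher, 4 lower of 18), with Gap43 at 6.90 and Tubb3 at -2.73. Oligodendrocyte genes had -0.17 (3 higher, 1 lower of 13, and 2 lower without p13 replicate 2), and Notch response genes 0.52, or 1.51 at the floor (4 higher, 2 lower of 9). Fibroblast genes had a median of -2.48 (32 of 38 lower, none higher), with Mfap5 at -5.45 and Col3a1 at -4.71. TGF-beta response genes had -2.31 (20 of 21 lower), with Tgfbi at -3.55, and Hox genes -2.09 (21 of 35 lower). Among 10000 random lists, the neural progenitor, forebrain and astrocyte medians lay at percentile 100 and the fibroblast, TGF-beta and Hox medians at percentile 0.

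Cell-cycle genes had a median of 1.53 against MEF (20 of 28 higher, none lower), with Ccnb1 at 2.54 (SE 0.12) and Pcna at 2.10 (SE 0.13). Cell-cycle inhibitors had -0.61 (2 higher, 5 lower of 13), with Gadd45b at -3.87 and Cdkn2c at 1.80. Hypoxia-response genes had -1.0 (2 higher, 14 lower of 28), with Ndrg1 at -3.36 and Adm at 1.65. Cholesterol synthesis genes had 0.67 (8 higher, 1 lower of 20), with Dhcr7 at 2.64. Wnt-response genes went both ways (median 0.94, or -1.04 over genes above background on all 5 arrays; 3 higher, 4 lower of 13), with Ccnd1 at 2.93 and Lef1 at -2.64. The pluripotency median was -0.28 (2 higher, 2 lower of 14; with 1 array left out, 1 to 3 higher): Esrrb rose by 5.68 and Tbx3 differed by -4.23, while Nanog, at -0.84, did not pass and Pou5f1 was under background on every array. Without ciNPC p13 replicate 2, Nanog passed at -1.08.

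Lists for other cell types were mixed against MEF. The interferon median was 1.23 (11 of 20 higher, none lower), with Rtp4 at 3.56 (SE 0.33). Epithelial genes had 0.40 (2 of 10 higher), neural crest genes -0.37 (1 higher, 2 lower of 12) and midbrain and hindbrain genes -0.89 (2 higher, 4 lower of 13). Macrophage genes had -0.44, or -0.05 at the floor (3 of 16 lower), endothelial genes -1.29, or -0.97 at the floor (4 of 8 lower) and muscle genes -0.01 (3 higher, 2 lower of 14). Housekeeping genes had a median of -0.25 (1 higher, 1 lower of 16, and 0 lower without ciNPC p5), and Tbp rose by 1.25. Scaling moved all genes alike: the median over all genes was -0.09 against MEF and -0.14 against NPC, and became 0.04 and -0.03 with a percentile over detected probes.

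ciNPC against NPC asks how far the cells matched the control progenitors. Col1a1 was at least 1100-fold higher in ciNPC (adjusted p 9.92e-07, 3 ciNPC arrays against 1). Acta2 was higher by 10.80 log2 units (SE 0.17, adjusted p 9.92e-07), the calcium-binding protein gene S100a6 by 10.31 (SE 0.19) and Col1a2 by 10.29 (SE 0.20). Inhba, Ltbp2, Actg2, Mgp and Cnn1 were also among the 10 highest, each at least 244-fold higher. Thy1 was higher by 5.96 (SE 0.17), and Twist2 at least 70.4-fold. The progenitor markers did not pass: Sox2 differed by -0.70 (SE 0.21, adjusted p 0.146), Olig2 by -0.79 (SE 0.15, adjusted p 0.0357, under 2-fold), Pax6 by -0.43, Nes by -0.42 and Fabp7 by -0.34. The pluripotency gene Nanog, at -0.13, did not pass either.

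In all, 792 genes passed against NPC, 778 higher and 14 lower, against 4967 for MEF. Lower genes numbered 22 without ciNPC p5, 43 without p13 replicate 1 and 76 without p13 replicate 2. Of the 778, 702 (90.2%) were at least 4-fold higher in MEF than in NPC, 724 (93.1%) were well above background on all 3 ciNPC arrays, and 335 (43.1%) had no probe well above background in NPC. The lowest genes were mostly dim in ciNPC: Dmrtc1a was at least 12.6-fold lower (adjusted p 0.0133) and Serpina5 at least 11.3-fold (0.0118). Trex2, Lilr4b, Defb30, Slurp1, Pxk and Slc35a5 were also among the 10 lowest. Tmem40 at -1.56 (SE 0.32, and -0.23 on its other probe) and Kcnj4 at -1.38 (SE 0.26) were above background on all 5 arrays. Neither passed under quantile normalisation. The 2 probes of Slc35a5 gave -2.66 and -0.36. Of the 4967 genes that passed against MEF, 4077 (82.1%) lay within 2-fold of NPC. Of the 792 that passed against NPC, 165 (20.8%) lay within 2-fold of MEF. The same shares among all genes tested were not counted. These percentages therefore do not show whether the genes that passed lay nearer the other cell type than genes at large.

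The lists separated fibroblast genes from neural ones against NPC as well. Fibroblast genes had a median of 5.23, or 4.63 with dim genes at the floor, and 31 of 38 were higher. Hox genes had 3.56, or 1.67 at the floor (23 of 35 higher), with Hoxb9 at least 28.2-fold higher. TGF-beta response genes had 2.20 (14 of 21 higher), with Thbs1 at 7.55 and Ccn2 at 7.52. Interferon genes had 3.61, or 2.59 at the floor (15 of 20 higher), and Oas1a was at least 84.6-fold higher. No member passed among neural progenitor (median -0.48 of 40), cell-cycle (-0.24 of 28), cholesterol (-0.47 of 20), Notch (-0.23 of 9), Wnt (-0.05 of 13) and housekeeping genes (-0.10 of 16), by limma; over all 16229 genes, 2943 had an unadjusted p under 0.05. Some calls appeared with 1 ciNPC array left out: the Wnt gene Fzd7 passed each time (1.28, 1.72 and 1.67), the progenitor and Notch gene Hes5 (-1.24) and the cholesterol gene Nsdhl (-1.02) without p13 replicate 1, and the Notch gene Heyl and the Wnt gene Rnf43, both under background in NPC, without p13 replicate 2. The neural progenitor and cholesterol medians lay at percentile 0 of the random lists, and the fibroblast, Hox, TGF-beta and interferon medians at percentile 100.

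Of the other lists against NPC, muscle genes had a median of 2.57, or 2.02 at the floor (10 of 14 higher), with Acta1 at least 38.8-fold higher. Macrophage genes had 2.44, or 1.15 at the floor and -0.16 over genes above background on all 5 arrays (5 of 16 higher), with Tyrobp at least 4.10-fold. Epithelial genes had 1.87, or 1.36 at the floor (3 of 10 higher), with Krt18 at 5.46. Neural crest genes had 1.13 (2 of 12 higher, and 4 without p13 replicate 2), including Snai2 at 5.18, and midbrain and hindbrain genes 0.55 (3 of 13 higher), including Irx1 at 5.20. Astrocyte genes had -0.11 (2 of 16 higher), oligodendrocyte genes -0.08 (2 of 13), neuron genes -0.20 (3 of 18) and forebrain genes -0.08 (1 of 15, Dlx2). Pluripotency genes had 0.29 (1 of 14 higher, Tbx3, and 2 without ciNPC p5 or without p13 replicate 2), hypoxia-response genes 0.07 (1 of 28, P4ha2), endothelial genes 0.07, or 0.57 at the floor (1 of 8, Flt1) and cell-cycle inhibitors 0.04 (2 of 13). With 1 array left out, the medians of hypoxia-response genes and cell-cycle inhibitors reached -0.06 and -0.07. None of these lists had a lower member, but Gap43 passed without p13 replicate 2 (-1.04) and Esrrb without p13 replicate 1 (-1.06).

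Adjusted over the list alone, most counts were those over all genes. Against MEF the exceptions were Hox (25 lower), immediate-early (7 lower), neural progenitor (2 lower), neuron (8 higher), Notch (3 lower) and Wnt (5 lower). Against NPC they were epithelial (4 higher), fibroblast (32), Hox (26), interferon (17), macrophage (7), muscle (11), neural crest (5), pluripotency (2) and sex-linked (1 lower). For p13 against p5 they were endothelial (1 higher), epithelial (1), forebrain (1) and pluripotency (2). Median and mean differed in sign for astrocyte, forebrain, neuron, Notch, oligodendrocyte and Wnt genes against NPC, and for muscle, oligodendrocyte and pluripotency genes against MEF. For p13 against p5 they differed for astrocyte, macrophage, Notch and Wnt genes. With dim genes at the floor, the medians of astrocyte (0.02), forebrain (0.14), oligodendrocyte (0.17) and Wnt genes (0.01) against NPC were above 0, as were those of muscle (0.15) and pluripotency genes (0.17) against MEF.

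**Figure D1:**
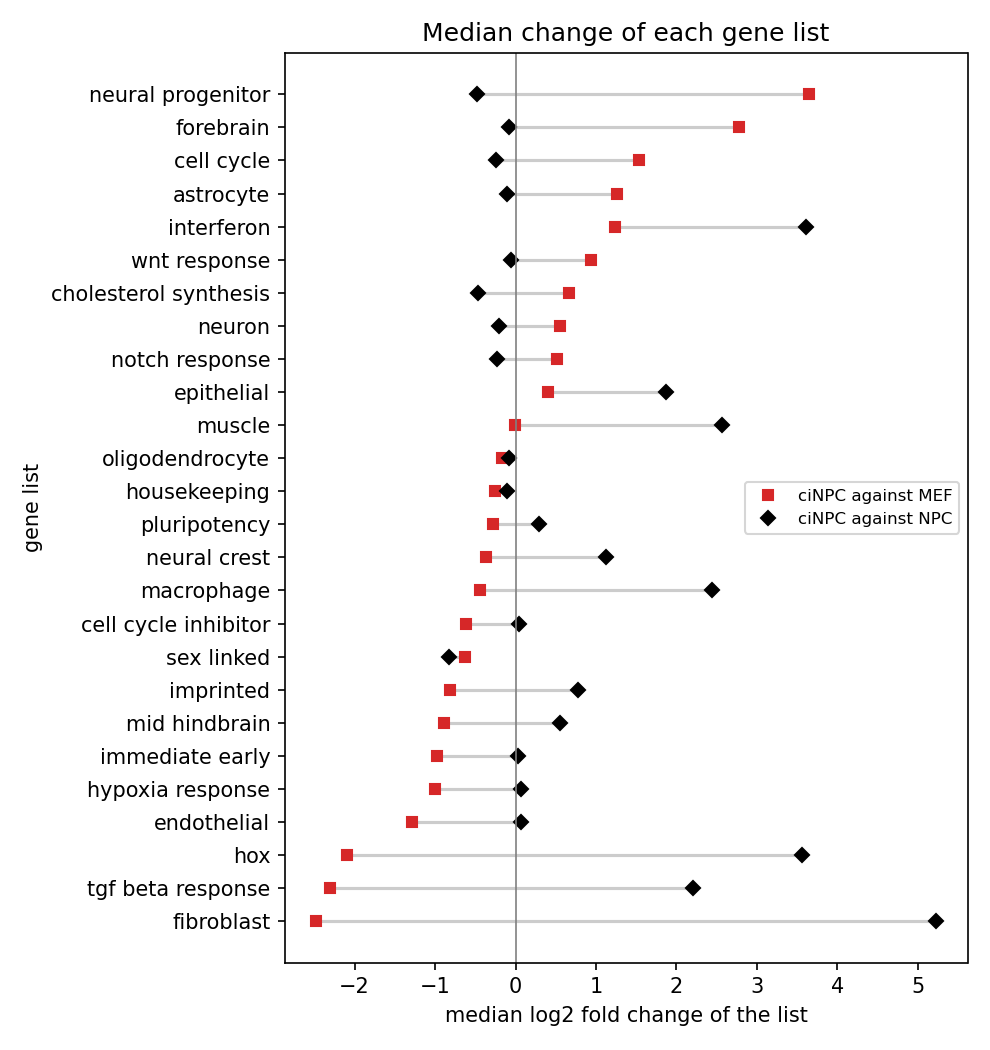
Median log2 difference of each of the 26 gene lists for the comparisons of ciNPC with MEF and with NPC. Fibroblast genes lie at -2.48 against MEF and 5.23 against NPC, and neural progenitor genes at 3.65 and -0.48.

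The position between MEF (0) and NPC (1) put both kinds of genes on 1 scale. Among the 1300 genes higher in NPC, the median position was 0.863 ± 0.014 (SD, n = 3 arrays), with 0.850 at p5 and 0.878 and 0.862 at p13. Among the 1637 genes higher in MEF it was 0.601 ± 0.033 (SD, n = 3), with 0.608 at p5 and 0.630 and 0.565 at p13. The gap between the classes was larger than the spread between arrays. In 20 simulations, cells identical to NPC gave 0.982 for NPC-high and 0.866 for MEF-high genes, and unconverted cells 0.109 and 0.022. A part of the gap between the classes therefore arose in cells identical to NPC too. Of the NPC-high genes 96.7% were at or past halfway, and of the MEF-high genes 65.1%. Col1a2, Acta2, Col1a1 and S100a6 were among the most different of the 93 MEF-high genes that stayed under 0.25 on all 3 arrays. Among NPC-high genes 3 did so: Defb30, Slurp1 and Ifna7. Position is a ratio of log2 distances, so a small residue of a gene very high in MEF counts for much. Col1a2 was at 12.5% of its MEF level. For genes at least 32-fold higher in NPC, ciNPC held a median of 68.1% of the NPC level. For genes at least 32-fold higher in MEF, ciNPC held a median of 11.4% of the MEF level. The order of the classes thus holds on the log2 scale only.

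**Figure D2:**
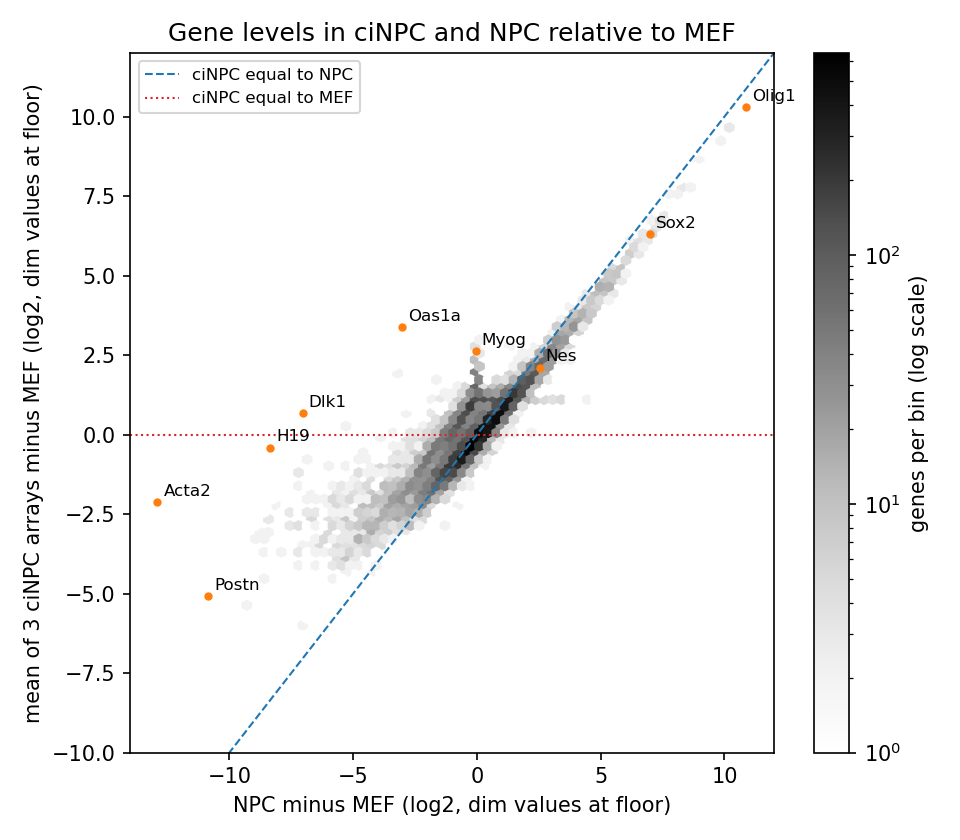
Log2 difference of ciNPC from MEF against that of NPC from MEF for each gene tested, with named genes marked. Genes higher in NPC lie near the line of equal values (median position 0.863), and genes higher in MEF lie farther from it (0.601). Simulated cells identical to NPC gave 0.982 and 0.866 for these classes, so a part of the gap is not a difference from NPC.

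Some genes lay outside the range of both MEF and NPC. Above both, 33 genes passed by limma. Independent calls would give 119.1, and 10 simulations of unchanged groups gave 0. Neither figure shows whether 33 is many or few, as unchanged groups give few calls to overlap. The comparisons also shared the ciNPC arrays, and NPC and MEF differed at least 4-fold in 2937 genes. The same limit holds for the other figures for independence below. The 33 became 50 without ciNPC p5 and 82 without p13 replicate 2. Flt4 was at least 8.64-fold higher than MEF and 8.99-fold higher than NPC, and the muscle factor Myog at least 6.18-fold and 6.43-fold. These bounds do not correct for the background of the ciNPC arrays. With dim values at the floor, genes dim in both MEF and NPC lay a median of 1.14 log2 units above NPC on those arrays. That value is set by the floors (-3.59, -3.23 and -2.81 on the ciNPC arrays, -4.35 on NPC) and does not measure background. Trim61 and Arhgap36 followed; without ciNPC p5, or without p13 replicate 1, Arhgap36, under background in MEF and NPC, no longer passed against NPC. Below both, 2 genes passed (2.1 if independent), and 6, 8 and 26 without ciNPC p5, p13 replicate 1 and p13 replicate 2. Of the 2, 1 had a symbol that the naming rule admits: Pxk, which was well above background on 1 of the 3 ciNPC arrays, so its fold is not given. Between them, 558 genes were lower than MEF and higher than NPC (119.0 if independent), and none was higher than MEF and lower than NPC (2.1 if independent).

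**Figure D3:**
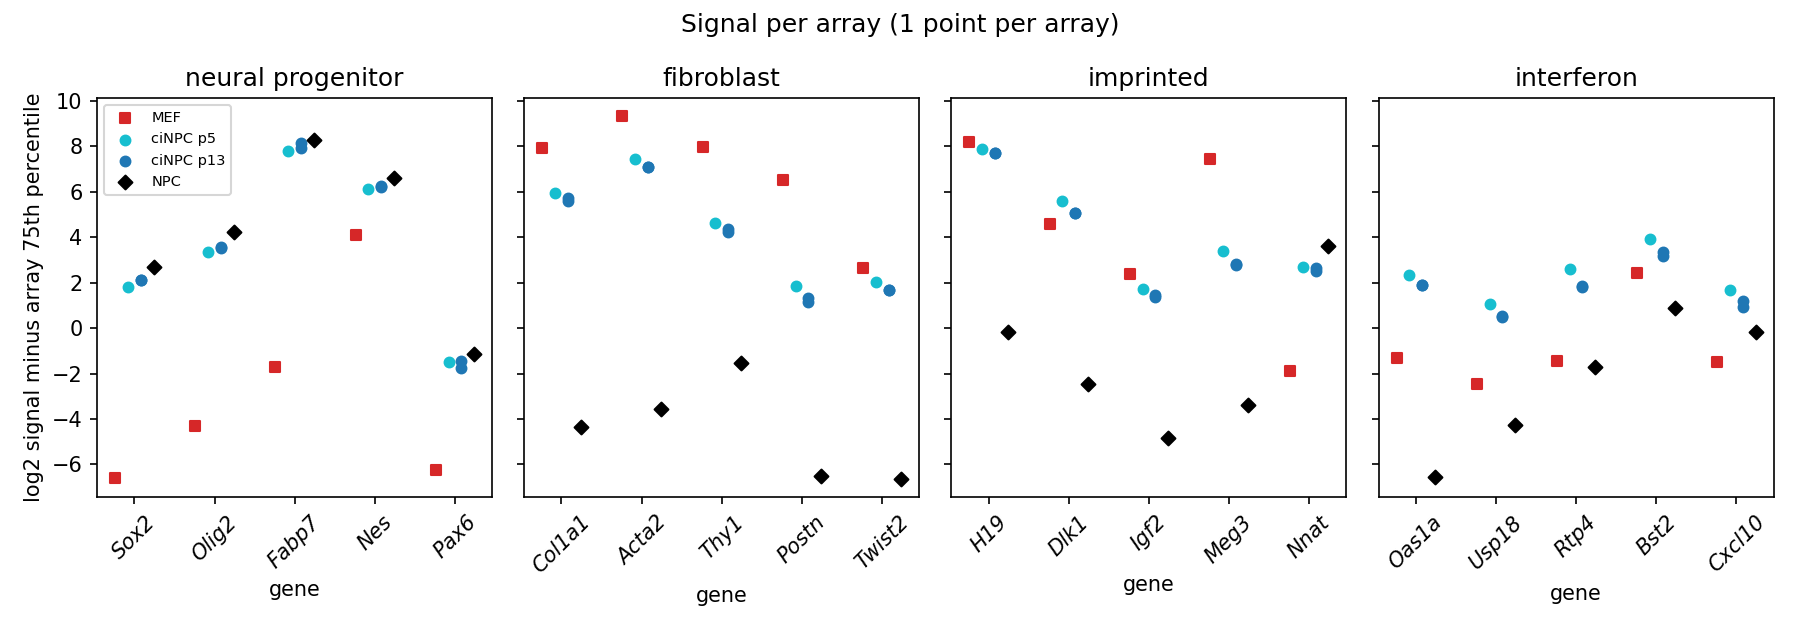
Scaled log2 signal of named genes on each of the 5 arrays, 1 point per array, for neural progenitor, fibroblast, imprinted and interferon genes. Sox2, Olig2 and Fabp7 in ciNPC lie near NPC, while Col1a1, Acta2 and Thy1 lie between MEF and NPC.

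ciNPC p13 against p5 asks what changed with passage. The prenyltransferase subunit gene Nus1, probed on chromosome 10 at 52156439 to 52156498, was higher at p13 by 5.27 log2 units (SE 0.13, adjusted p 3.15e-09, 2 arrays against 1). Nus1 was at -3.21 on the p5 array and between 1.88 and 3.11 on the other 4, and its other probe differed by only 0.37 between passages, so a defect of 1 spot is not excluded; the mean of its probes gave 2.82. Trh was at least 7.45-fold higher (adjusted p 0.00195), Gpr39 at least 7.0-fold (0.0173) and Sdr9c7 at least 4.83-fold (0.0271), and Kcnk16 also passed (0.044). Eya2 differed by -2.36 (SE 0.18, adjusted p 0.000169) and Tmsb15b1 by -2.19 (SE 0.55; -0.21 on its other probe; above background on 1 of 2 p13 arrays). Map3k7cl was at least 11.6-fold lower at p13 (0.0186), Cyp27b1 at least 6.56-fold (0.04) and Fam199x at least 5.65-fold (0.0123). Hypoxia-response genes had a median of -0.28, and Bnip3 (-1.64), Pdk1 (-1.30) and Vegfa (-1.03, and -0.39 on its other probe) were lower. Hes5 (1.12), Atp1b2 (1.27), Elavl3 (1.37), En2 (1.13) and Nanog (1.09) were higher, and Egr2 (-1.37) and Lgr5 (-1.08) lower; the mean of the Nanog probes gave 0.08.

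In all, 103 genes passed between passages, 69 higher and 34 lower at p13. The split was 31 and 59 with normexp and quantile normalisation, 2 genes passed with quantile normalisation, and without the intensity trend limma gave 0, with 1479 genes at an unadjusted p under 0.05. At least 4-fold apart were 59 genes between p13 replicate 1 and p5, and 102 between replicate 2 and p5, against 46 between the p13 arrays. By list, no member passed among fibroblast (median -0.46), TGF-beta (-0.35), Hox (-0.38), interferon (-0.46), muscle (-0.39), cell-cycle (-0.04) and cholesterol genes (0.22), by limma, with 3633 genes at an unadjusted p under 0.05. The neural progenitor median was 0.25. Among the random lists, the fibroblast, TGF-beta, Hox, interferon and hypoxia-response medians between passages lay at percentile 0. The cholesterol and neural progenitor medians lay at percentile 100. These percentiles do not measure the spread between arrays, and p5 was 1 array. For MEF-high genes as a class, the position at p5 (0.608) lay between those of the p13 arrays (0.630 and 0.565). Epithelial genes had 0.85, endothelial 0.55 (-0.13 over genes above background on all 5 arrays), forebrain 0.28, mid- and hindbrain 0.39, Notch 0.30, pluripotency 0.31, neuron 0.12, astrocyte 0.09, oligodendrocyte 0.19, housekeeping 0.08, Wnt -0.02, macrophage -0.02 and neural crest genes -0.20.

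Across genes, ciNPC correlated with NPC at Pearson r 0.929 (p5), 0.947 (p13 replicate 1) and 0.936 (p13 replicate 2). The correlation with MEF was 0.871, 0.869 and 0.873 in the same order, and that of MEF with NPC was 0.789. Between the p13 arrays r was 0.979, and between p5 and the p13 arrays it was 0.982 and 0.966. The difference between 0.937 (mean with NPC) and 0.871 (mean with MEF) was larger than the SD over the 3 arrays, 0.0095 and 0.0019. 10 pairs of arrays were compared, and MEF and NPC shared a slide that the ciNPC arrays did not.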

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

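All tests of explanations in this part were chosen after the results they measure had been seen.

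Between ciNPC p13 and p5, 103 genes passed, Eya2 (-2.36) among them, but the count depended on the processing. It was 2 with quantile normalisation, 2 with the authors' value table and 0 in limma without an intensity trend (1479 genes at an unadjusted p under 0.05), and simulated data gave a mean of 21 false calls. The difference was tested directly in limma, with the spread of 2 p13 arrays and 1 residual degree of freedom. The largest difference, Nus1 (5.27), came from 1 probe that was low on the p5 array alone, at -3.21 against 1.88 or more on the other 4. The other Nus1 probe gave 0.37, so a defect of 1 spot is not excluded. No biological explanation was tested for this difference.

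Signal also appeared in data that the comparisons left out. Of 8820 names on the array that the reference table does not hold and that were above background, 95 were higher on the ciNPC arrays than on the NPC array and 7 were lower. None of these names is described singly here.

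Interferon-response genes lay above both MEF and NPC on the ciNPC arrays. Of 20 genes tested, 17 were above both in sign and 9 passed above both, among them Rtp4 (3.56 against MEF) and Oas1a (3.38 against MEF). The 9 became 6 without ciNPC p5, 7 without p13 replicate 1 and 9 without p13 replicate 2; Xaf1 and Ifit1 lost their call against MEF in the first and second of these, and Bst2 (0.84) in the first. The values argued against scaling between arrays as the cause: the lowest median of the list against MEF over 4 scaling alternatives was 0.92. The slide or scan of the ciNPC arrays cannot be told apart from a response of the cells, since all 3 ciNPC arrays shared slide 2, so the 9 genes do not decide between them. A response of ciNPC to their culture may explain the pattern and was not tested; a ciNPC array on slide 1 would separate it from the slide.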

How the results depend on the processing

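The percentile over detected probes and the use of all names on the array were chosen after seeing the data; the other alternatives were chosen before. For values given without a cause, the cause was not tested.

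The count against MEF stayed within 1.5 times of 4967 under every alternative, from 4004 to 6347, and from 4704 to 5631 when 1 ciNPC array was left out. The count against NPC, 792, ran from 436 to 989 and from 938 to 1107 when 1 array was left out. The 436 came from genes above background on all 5 arrays, which removes the genes dim in NPC.

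The count for p13 against p5 (103) depended most on the processing. It was 2 with quantile normalisation, 2 with the authors' value table, 58 with genes above background on all 5 arrays, 179 with the mean of all probes, 207 with a floor, 0 in limma without an intensity trend (1479 genes at an unadjusted p under 0.05) and 637 (401 higher, 236 lower) with the size rule. The genes shared with the 103 were 2, 2, 58, 83, 99 and 0 in the first 6 of these. The cause was not tested.

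Genes past the threshold the same way against both numbered 14 with genes above background on all 5 arrays, 67 in the fit with 4 groups, and 49 to 108 when 1 ciNPC array was left out. Genes at least 4-fold apart between NPC and MEF numbered 1829 with normexp, 1839 with genes above background on all 5 arrays and 6813 at 2-fold.

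The position of NPC-high genes (0.863) was 0.879 with normexp, 0.884 with the authors' table, 0.896 with the percentile over detected probes, 0.824 at 2-fold, and 0.856 to 0.870 when 1 array was left out. That of MEF-high genes (0.601) was 0.660 with quantile normalisation, 0.673 with normexp, 0.656 with the authors' table, 0.660 with genes above background on all 5 arrays, 0.568 with the percentile over detected probes, 0.663 at 2-fold, 0.564 with no floor, and 0.586 to 0.619 when 1 array was left out. On this log2 scale, NPC-high genes lay nearer NPC than MEF-high genes in each of these, as they did in simulated cells identical to NPC (0.982 and 0.866).

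The mean correlation with NPC (0.937) was 0.967 with normexp, 0.956 with no filter, 0.961 with genes above background on all 5 arrays and 0.953 by Spearman. With MEF (0.871) it was 0.899 with normexp, 0.919 with no filter and 0.892 with all names. Between MEF and NPC (0.789) it was 0.837 with normexp, 0.883 with no filter, 0.835 with all names and 0.808 by Spearman.

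Some list medians changed sign. Against NPC the cell-cycle inhibitors were at -0.01 without p13 replicate 1 and ran from -0.07 to 0.06 when 1 array was left out, hypoxia-response genes from -0.06 (without p5) to 0.13, and immediate-early genes from -0.08 (without p5) to 0.11. With genes above background on all 5 arrays, which leaves fewer members, endothelial genes were at -0.13 for p13 against p5, macrophage genes at -0.16 against NPC and Wnt genes at -1.04 against MEF. Lhx6 against MEF was 0.16 with the mean of its probes. Among values of named genes against MEF, 3351 kept their side of the threshold, 109 lost it and 88 gained it; against NPC these were 3369, 112 and 68, and for p13 against p5 2398, 82 and 13.

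No paired analysis was possible because the groups share no more than 1 replicate number. Slide as a block was not run, since each cell type lies on 1 slide only. Leaving out a p13 array left no residual degrees of freedom for p13 against p5, and the groups are too small for other splits of the samples. Signal over background limits the genes dim in 1 cell type, whose folds are lower bounds.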

Other observations

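All tests of explanations in this part were chosen after the results they measure had been seen, and the second test of dilution, the second test of the MEF culture and its values by array were added after the first had been run.

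Imprinted genes went both ways against MEF. H19, a growth-limiting non-coding RNA, was higher in ciNPC than in NPC by 7.95 log2 units (SE 0.13, adjusted p 9.92e-07), and Dlk1 by 7.73 (SE 0.23), while both lay within 2-fold of MEF (-0.41 and 0.68). Meg3 lay between, at -4.47 against MEF and 6.38 against NPC, and Igf2 was at least 58.3-fold higher than NPC. Nnat rose by 4.50 against MEF and was at -0.99 against NPC, where it passed without ciNPC p5 (-1.02) and without p13 replicate 1 (-1.01). Of 19 imprinted genes tested, 4 were higher and 8 lower than MEF (median -0.81), and 7 were higher than NPC (median 0.78). None passed for p13 against p5 (median -0.27), by limma, with 3633 of all genes at an unadjusted p under 0.05.

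Of 3 sex-linked genes tested, Xist was higher in ciNPC than in MEF by 1.21 (SE 0.26) and Ddx3y differed by -1.80 (SE 0.25), and none passed against NPC or between passages (medians -0.63 against MEF, -0.83 against NPC, 0.38 for p13 against p5), by limma. Eif2s3y passed against NPC without p13 replicate 1 (-1.27) and without p13 replicate 2 (-1.38). Immediate-early genes had a median of -0.97 against MEF (6 of 14 lower), with Fosb at -4.27, and 0.03 against NPC (2 of 14 higher, Fosl1 and Klf2). Between passages Fosb (-1.50) and Atf3 (-1.30) were lower at p13 (median of the list -0.18).

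Genes high in NPC lay below the NPC array by a like ratio: for 174 genes at least 32-fold higher in NPC than in MEF, the median log2 difference of ciNPC from NPC was -0.56 (quartiles -0.65 and -0.44), and 100% were below NPC. By array the median was -0.72 at p5 and -0.40 and -0.55 at p13. The 174 genes were chosen on the same NPC array, which alone may place ciNPC lower. Simulated cells identical to NPC also fell short, at a position of 0.982 for genes at least 4-fold higher in NPC. The size of this effect was not simulated for the 174 genes, and the alike genes below were not chosen this way. The values argued against scaling between arrays as the whole cause, since the median was -0.37 (95% interval -0.40 to -0.35) from that of genes alike in MEF and NPC. By array, those alike genes lay nearer NPC, at -0.15, -0.17 and -0.22 for p5, p13 replicate 1 and p13 replicate 2. The values argued against the compressed range of p13 replicate 2 as well, since the other ciNPC arrays gave -0.55 together (-0.57 to -0.51). These intervals resampled genes and do not measure the spread between arrays. On their own, p5 and p13 replicate 1 each lay below NPC, at -0.72 and -0.40. NPC-like RNA diluted by RNA of other cells may give such a ratio: the SD over genes was 0.41 times that between p13 and p5, but in a stricter test, 1.74 times that between the p13 arrays on the array with the widest spread, which leaves it open. Lower expression in ciNPC stays open as well, and slide cannot be told apart from either.

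Genes high in MEF stayed above the NPC array. For 354 genes at least 32-fold higher in MEF, ciNPC held a median of 11.4% of the MEF level (10th to 90th percentile 3.6% to 32.6%), with Twist2 at 56.2%, H19 at 75.4% and Postn at 3.0%. With dim values at the floor, these genes lay 3.37 log2 units above NPC. That was 2.23 more than the 1.14 of 6004 genes dim in both cell types. The 1.14 is set by the floors of the arrays, higher on ciNPC (-3.59, -3.23 and -2.81) than on NPC (-4.35). The comparison shows only that the median of the MEF-high genes was not signal at the floor. It cannot tell how far a higher background of the ciNPC arrays lifts signal above the floor. Background may thus give a part of the rise, and its share was not measured. The values argued against the MEF culture as diluting cells that fill the whole open share. Of the MEF-high genes, 64.1% (95% interval 59.3% to 69.5%) lay under 50% of the level that the open share of 31.9% needs. That level takes the whole shortfall of NPC-high genes as diluting RNA, although lower expression and slide stay open for it. A smaller share of MEF RNA was not tested. The intervals here resampled genes and do not measure the spread between arrays. With the shift of genes alike in MEF and NPC taken out of both sides, the open share was 22.8%, the median level 13.1% of MEF, and 46.0% of the genes (40.4% to 51.7%) lay under 50% of the level needed, above the 25% set as the limit. The open share varied by array, at 39.2%, 24.3% and 31.9% for p5, p13 replicate 1 and p13 replicate 2, or 32.5%, 14.8% and 20.5% with the shift taken out, with which 50%, 34.7% and 42.1% of the genes lay under 50% of the level needed. On p13 replicate 1 the interval (24.6% to 42.1%) reached the limit, so that array alone does not exclude the MEF culture as the source of the whole open share. Incomplete silencing within the same cells may give unequal shares, and the 10th and 90th percentiles differed 9.1 times, but fibroblast-like cells unlike the MEF array would give them too, and bulk RNA cannot separate these; single-cell measurement would.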
